A study of Homo sapiens with 6 samples.

How the data were processed

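RNA was sequenced from primary adult human erythroid cells on day 11 of culture, in 3 libraries treated for 7 days with 0.25 µM UNC0638 and 3 treated with DMSO. Per the labels' protocols, total RNA was extracted with a spin column kit and libraries were made from 50 to 100 ng of total RNA with the NEBNext Ultra RNA kit. The submitters' processing notes name TopHat2 2.0.13 and TopHat for alignment, HTSeq 0.6.1p1 for counting, edgeR with no version, and the genome build hg19. The annotation release and whether counting used strand are not given in the sources used here. Libraries were named by their group and the replicate number in the labels. Numbers in the sample titles are not consecutive and are shared between the groups, and the labels do not say what they mark.

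The authors deposited a single table of gene values whose unit was treated as a signal, namely read counts with decimals that had been normalized by trimmed means of M values (TMM) and equalized to a common library size. The name TMM is per the file name, and the equalization was inferred here from the values. The table held 12267 gene rows and 2 rows that name no gene. Those 2, reads in no feature (10.3% to 12.1% of a library) and ambiguous reads (4.56% to 4.98%), were left out of sums and tests. The lowest maximum of any gene was 23.1 normalized counts, so low genes had been removed before deposit and a gene without a row was not analysed here. No pair of libraries held identical values.

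Steps of a single size per library did not give whole reads, so no count model was run. The authors' equalization was undone as edgeR defines it, with an assumed dispersion of 0.01. This turned 95.9% to 100% of low values per library (those under 30) into whole numbers within 0.1, and gave relative depths of 0.78 to 1.21. These depths set the estimate of 14.1 to 21.8 M assigned reads per library, which rests on that model. They were used to describe precision and to simulate data, and entered no test.

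All values were divided by 18.4 M, the mean of the libraries' gene totals, which gives counts per M (CPM) and leaves the authors' scaling between libraries as it was. The design fixed before the data were examined asked for division to CPM of the summed table, and a single divisor was the reading that kept the TMM scaling. Division by each library's own sum was tried as an alternative. Genes at 1 CPM or more in at least 3 libraries were kept, which removed none. Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend and robust variance, the group as the only factor, 4 residual degrees of freedom per gene and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The fetal share was compared with a two-sided exact permutation test.

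Gene lists, 30 in number with 578 entries, were written before the data were examined, and 29 had at least 3 measured members. Each was tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation as an alternative. Of the 9 lists called (7 up, 2 down), 0 held with the estimated correlation. Limma's fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, called 11 up and 1 down. The rule for named genes, also fixed in advance, took the globins, EHMT1, EHMT2 and a set of globin regulators. It added the 10 largest rises and 10 largest falls among genes past the test with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out genes without a symbol, and the 2 to 4 list members with the smallest adjusted p. Members beyond these, and BGLT3, the class II genes and library values of single genes, were chosen after their values were seen. A blood group gene and some class II genes whose level can reflect a donor's genotype were left unnamed, and Y-linked genes and genes of X inactivation are not reported. Symbols were found for 11967 of the identifiers. Coordinates, length and GC content came from GENCODE release 29 on GRCh38 for 11967 genes, 97.6% of all, while the authors aligned to hg19.

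The fit was tested on simulated data drawn from the real means and estimated depths, with a dispersion of 0.01 and 200 changed genes among 12226 tested. For UNC0638 against DMSO it recovered 86.6% of genes changed 1.5-fold, 100% of those changed 2-fold and 100% of those changed 4-fold, with 11 false calls among 202. A list of 20 genes raised 1.5-fold was called, and 0 of 200 random lists were. The changed genes and the raised list were taken from genes with a mean of at least 5 CPM, so recovery of lower genes was not simulated. Genes were drawn independently, at a single dispersion and with no library set apart, so these rates need not hold for the real libraries.

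Alternatives fixed in advance were pseudocounts of 0.25 and 5, no filter and a filter of 5 CPM, median-of-ratios, fixed-sum and quantile scaling, limma without trend or robust variance, the replicate number as a block, and leaving out each library in turn. Library quality weights and a correction for GC content and transcript length (natural splines per library) were added after the data were seen. Scripts also used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.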

Results

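Gene expression was measured by RNA sequencing in primary adult human erythroid cells, the red cell precursors grown in culture from CD34+ blood stem and progenitor cells. The cells were collected on day 11 of a 3-phase culture, after 7 days with either 0.25 µM UNC0638 or its vehicle DMSO. UNC0638 is a small-molecule inhibitor of EHMT1 and EHMT2, a pair of enzymes that methylate histone H3 and repress transcription. Each group held 3 libraries, called biological replicates by the submitters. The labels do not say whether these came from separate donors or separate cultures, so p-values measure only the spread between these libraries. The series title names fetal hemoglobin. The comparison of UNC0638 with DMSO asks which transcripts, the fetal globins among them, differ after inhibition of the enzymes.

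The deposited values were normalized counts with decimals, expressed here as normalized counts per M (CPM). Fold changes were taken on the log2(value + 1) scale, so for low genes they are smaller than the ratio of the CPM means. Their sum over genes was 18 to 20.3 M per library. The reads assigned to genes were estimated at 14.1 M in DMSO replicate 2, the shallowest library, and at 21.8 M in DMSO replicate 3, the deepest. A single read stood for 0.0447 to 0.0695 CPM. The first principal component of the log2 values held 69.0% of the variance. It placed the UNC0638 libraries between 20.1 and 23.7 and the DMSO libraries at -37.7, -14.2 and -12.8. DMSO replicate 1 stood apart from the rest of its group. The SD across genes of its log2 difference was 0.387 to DMSO replicate 2 and 0.399 to DMSO replicate 3. The same SD was 0.151 between those libraries and 0.159 to 0.183 between the UNC0638 libraries.

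**Figure D1:**
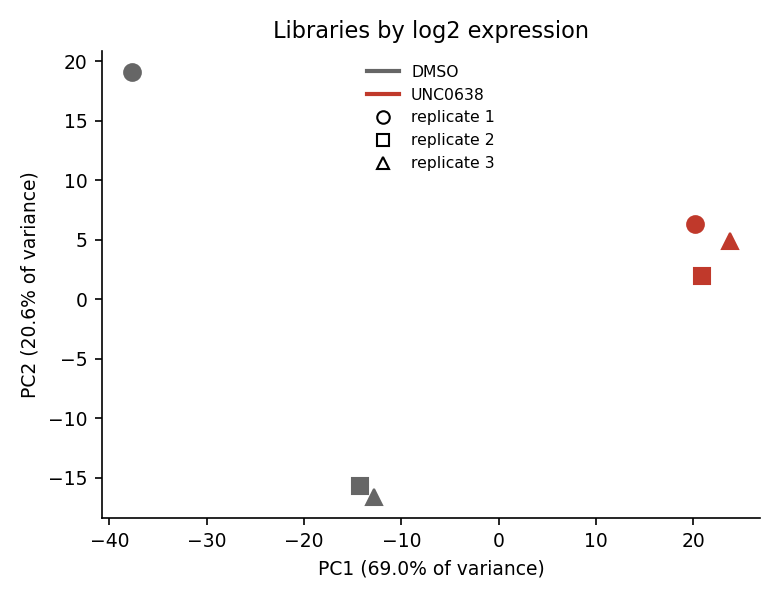
First and second principal components of the log2 expression values of the 6 libraries, with the percent of variance on each axis, color for the group and symbol for the replicate number. The UNC0638 libraries lie at 20.1 to 23.7 on the first component, and DMSO replicate 1 lies at -37.7, away from the other DMSO libraries.

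Fetal globin transcripts were higher in the UNC0638 libraries. HBG1, which encodes a gamma chain of fetal hemoglobin, rose 3.45-fold, from 340 ± 144 CPM (SD, n = 3) with DMSO to 1115 ± 52.2 with UNC0638. Its log2 fold change was 1.79 (SE 0.24, limma adjusted p = 0.0031). HBG2, the other gamma chain gene, rose 2.05-fold, from 593 ± 260 to 1149 ± 59.7 CPM, with a log2 fold change of 1.04 (SE 0.25, limma adjusted p = 0.0297). The fetal share is HBG1 and HBG2 as a percent of all beta-like globin transcripts (HBG1, HBG2, HBB, HBD and HBE1). It was 3.30% ± 0.52 (SD, n = 3) with DMSO and 11.1% ± 0.45 with UNC0638, a difference of 7.80 percentage points and a ratio of 3.36. A two-sided exact permutation test over 20 assignments gave p = 0.1, the smallest p that 3 against 3 allows. The DMSO libraries had fetal shares of 3.90%, 3.06% and 2.96% and the UNC0638 libraries 11.1%, 10.7% and 11.6%. The groups thus did not overlap and lay farther apart than the libraries within them. Because HBG1 and HBG2 are nearly identical, how the authors' counting divided reads between them is uncertain. Their sum was 933 ± 403 CPM with DMSO and 2263 ± 111 with UNC0638, and HBG1 made up 36.6% ± 0.56 and 49.3% ± 0.35 of it. The HBG1 call was kept without each library in turn. That of HBG2 was lost without DMSO replicate 2 (limma adjusted p = 0.0768) or DMSO replicate 3 (0.0633), and without UNC0638 replicate 1, 2 or 3 (0.101, 0.092 and 0.128).

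Adult globins did not pass the test. HBB, the adult beta chain, was at 25883 ± 6609 CPM with DMSO and 17692 ± 59.0 with UNC0638, with a log2 fold change of -0.52 (SE 0.19, limma adjusted p = 0.097). HBD, a minor adult chain, had a log2 fold change of -0.54 (SE 0.24, adjusted p = 0.149). HBB took 3.05% of all normalized counts in DMSO replicate 1 against 2.25% and 2.26% in the other DMSO libraries. Without DMSO replicate 1, HBB (log2 fold change -0.32, adjusted p = 1.03e-09) and HBD (-0.23, adjusted p = 9.87e-05) passed. Both also passed with library quality weights (adjusted p of 2.52e-06 and 0.00273) and with a correction for GC content and length (0.00828 and 0.04996). The alpha chain genes HBA1 (-0.20, adjusted p = 0.503) and HBA2 (-0.19, adjusted p = 0.494), also nearly identical, did not pass. Their values were 0.05 and 0.04 without DMSO replicate 1. HBE1, the embryonic epsilon chain, was low in both groups at 5.2 ± 2.15 and 5.32 ± 1.19 CPM (log2 fold change 0.07, SE 0.25, adjusted p = 0.866). It changed sign without DMSO replicate 2 (-0.14) or UNC0638 replicate 1 (-0.08), and passed with quality weights (0.44, adjusted p = 0.00471). HBBP1, a pseudogene of the beta globin locus, did not pass (0.41, adjusted p = 0.343) except with quality weights (0.76, adjusted p = 0.0382). HBM, a gene of the alpha globin locus, fell 1.85-fold (log2 fold change -0.89, SE 0.21, adjusted p = 0.0247). This call was lost without UNC0638 replicate 1, 2 or 3 (adjusted p of 0.0825, 0.0917 and 0.111).

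Of 3 measured fetal and embryonic globins 2 rose and 0 fell (2 and 0 adjusted over the list alone). Of 4 adult globins 0 passed (0 adjusted over the list alone), and of 3 other globin-locus genes, HBM, HBQ1 and HBBP1, 0 rose and 1 fell (0 and 1 adjusted over the list alone). These 3 lists did not pass limma's camera test (adjusted p of 0.0841, 0.23 and 0.522), but the fetal and embryonic globins passed without DMSO replicate 1 (0.000312). They also passed with quantile normalization (0.0439), library quality weights (0.00119) and a correction for GC content and length (0.0257). HBZ was not analysed here. Coordinates are those of GRCh38 from the GENCODE annotation, while the authors used hg19. HBG1 (ENSG00000213934) lies on chromosome 11 from 5248079 to 5249859, and HBB (ENSG00000244734) from 5225464 to 5229395. The annotated HBG2 gene (ENSG00000196565) runs from 5253190 to 5505605 and overlaps HBE1, from 5268345 to 5505652, so that reads in shared sequence are uncertain.

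**Figure D2:**
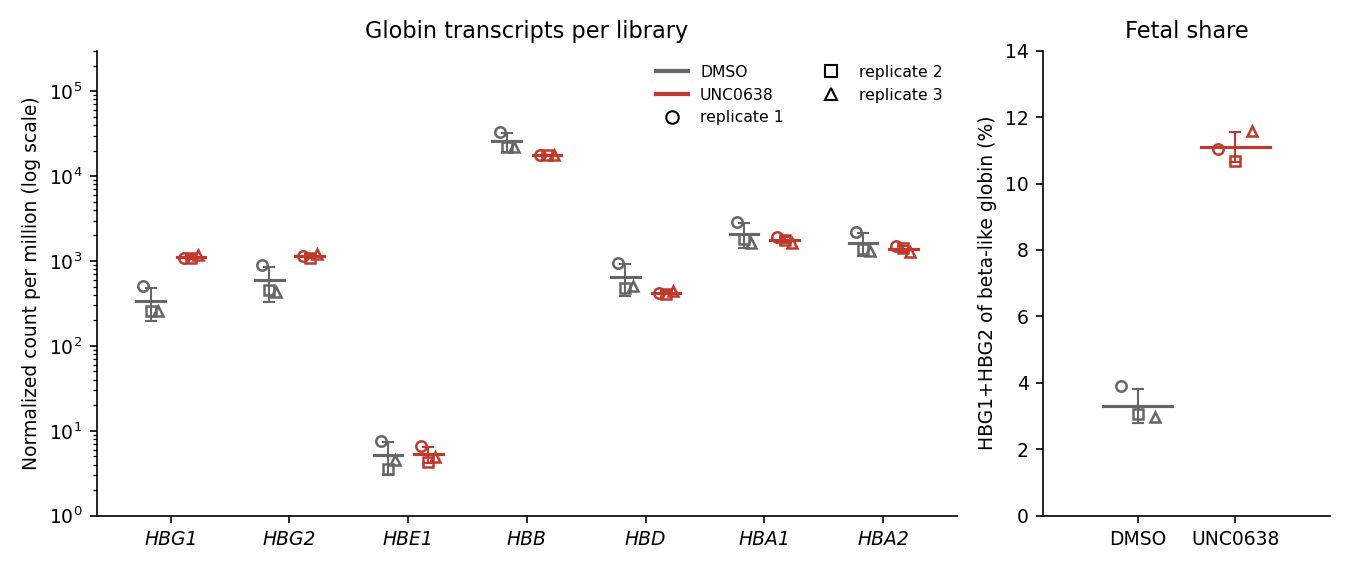
Left, normalized counts per M on a log scale of the globin genes in each library, by group (color) and replicate (symbol), with the group mean as a line and the SD (n = 3) as error bars. Right, HBG1 and HBG2 as a percent of beta-like globin transcripts, at 3.30% ± 0.52 with DMSO and 11.1% ± 0.45 with UNC0638.

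Of the regulators of fetal globin named in advance, SOX6, a transcription factor that represses gamma globin together with BCL11A, rose 1.86-fold. It went from 39.1 ± 7.90 to 72.6 ± 3.83 CPM (SD, n = 3), with a log2 fold change of 0.89 (SE 0.15, limma adjusted p = 0.00709). Transcripts of the drug's targets did not pass, with log2 fold changes of -0.06 for EHMT1 (SE 0.08, adjusted p = 0.594) and -0.18 for EHMT2 (SE 0.07, adjusted p = 0.129). EHMT2 passed without DMSO replicate 1 (-0.15, adjusted p = 0.0161) and with library quality weights (-0.16, adjusted p = 0.00292). EHMT1 passed with those weights (-0.12, adjusted p = 0.0195) and with the GC and length correction (-0.18, adjusted p = 0.0274). Transcript levels do not measure the activity of these enzymes. BCL11A, the main repressor of gamma globin, was at 75.8 ± 10.9 and 92.3 ± 6.13 CPM (0.29, SE 0.12, adjusted p = 0.127), and it passed without DMSO replicate 1 (0.17, adjusted p = 0.0197) and with quality weights (0.14, adjusted p = 0.0246). ZBTB7A (0.10, adjusted p = 0.477), MYB (-0.26, adjusted p = 0.0677), KLF1 (-0.10, adjusted p = 0.639) and GATA1 (-0.18, adjusted p = 0.377) did not pass. MYB passed without DMSO replicate 1 (-0.32, adjusted p = 1.45e-05), where KLF1 had the other sign (0.07). MYB also passed with quality weights (-0.34, adjusted p = 5.57e-07) and with the GC and length correction (-0.33, adjusted p = 0.00367), where KLF1 passed with the other sign (0.20, adjusted p = 0.0251). LIN28B and IGF2BP1 were not analysed here.

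Of 26 measured reported regulators of fetal globin, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.499). Besides SOX6, the chromatin protein HMGA2 rose 1.35-fold (adjusted p = 0.0253), and the arginine methyltransferase PRMT5 fell 1.31-fold (adjusted p = 0.0162). The calls of HMGA2 and PRMT5 were lost without DMSO replicate 2 (adjusted p of 0.0646 and 0.0504). They were also lost without each UNC0638 library (0.093 to 0.111 for HMGA2 and 0.0609 to 0.0847 for PRMT5). HMGA2 lost its call with the GC and length correction (0.234) and PRMT5 with a fixed sum of all genes (0.0547). Of 15 erythroid transcription factors 4 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.632). The rises were FOXO3 (log2 fold change 0.63, adjusted p = 0.0221), KLF3 (0.58, adjusted p = 0.0405), E2F2 (0.36, adjusted p = 0.0206) and TAL1 (0.33, adjusted p = 0.0224). These 4 calls were each lost without any 1 of the UNC0638 libraries (adjusted p of 0.067 to 0.152), that of E2F2 also without DMSO replicate 3 (0.0553), and that of TAL1 without DMSO replicate 2 (0.0574) or 3 (0.054). KLF3 also lost its call with fixed sums (0.0661 without globin genes and 0.0687 over all genes) and with limma without trend or robust variance (0.0513). Without DMSO replicate 1, 9 regulators of fetal globin rose and 6 fell, and 7 erythroid transcription factors rose and 5 fell.

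Over all 12267 genes tested, 1059 rose and 1044 fell (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes made up 209 of the rises and 138 of the falls. CCDC26, a long noncoding RNA gene, had the largest rise under the naming rule, from 0.518 ± 0.28 to 11.9 ± 0.16 CPM (SD, n = 3). On the log2(value + 1) scale that was 8.56-fold, with a log2 fold change of 3.10 (SE 0.15, adjusted p = 5.28e-05). The noncoding LINC01088 rose 7.93-fold, the zinc finger gene ZNF462 5.97-fold, PPFIA4 5.87-fold, NXF3, of an mRNA export factor family, 5.73-fold, and the noncoding MIR210HG 5.66-fold. PFKFB4, a regulator of glycolysis, rose 5.06-fold (2.34, SE 0.39, adjusted p = 0.00752). The transporter gene SLC16A9 rose 4.90-fold, the transcription factor BHLHE40 4.70-fold and TSPYL5 4.69-fold. CCDC26 and LINC01088 were under 1.25 CPM, the lowest maximum of any gene, in every DMSO library. Their rows thus rest on the UNC0638 libraries. PPFIA4, MIR210HG, PFKFB4 and BHLHE40 varied between the UNC0638 libraries, with SDs of 12, 19.2, 54.2 and 39.6 around means of 21.8, 50.2, 94.2 and 104 CPM. The call of PFKFB4 was lost without DMSO replicate 1 (adjusted p = 0.0605).

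The largest fall was that of TACC2, a centrosome-associated gene, from 18.7 ± 1.68 to 0.429 ± 0.1 CPM (SD, n = 3). On the log2(value + 1) scale it was 13.8-fold lower, with a log2 fold change of -3.79 (SE 0.12, limma adjusted p = 1.42e-05). The zinc finger genes ZSCAN18 (6.26-fold lower), ZNF528 (6.17-fold), ZNF880 (5.92-fold) and ZNF667 (5.51-fold), all on chromosome 19, were among the 10 largest falls, as was ZNF667-AS1 (5.31-fold). ZNF667 and ZNF667-AS1 are antisense partners. Without strand information, which is not given in the sources used here, their reads cannot be assigned with certainty. TPSG1, a tryptase gene, was 5.99-fold lower, SLC6A19, an amino acid transporter, 5.13-fold, the receptor kinase AXL 4.42-fold, and LGALS1, which encodes galectin-1, 4.40-fold. LGALS1 was at 45.1 CPM in DMSO replicate 1 and at 18.9 and 17.7 in the other DMSO libraries, against a mean of 4.92 ± 1.00 with UNC0638. TACC2, ZSCAN18, ZNF880, ZNF667 and ZNF667-AS1 were under 1.25 CPM, the lowest maximum of any gene, in every UNC0638 library. Their rows thus rest on the DMSO libraries.

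At an unadjusted p under 0.05 there were 4198 genes. The groups' libraries did not overlap for 5746 genes, or 46.8%, where chance gives 10%. Without DMSO replicate 1, 2525 genes rose and 2495 fell, and without DMSO replicate 2, 721 rose and 695 fell. Without UNC0638 replicate 1, 2 or 3, 408, 470 and 381 rose and 375, 401 and 362 fell. Library quality weights gave 3118 rises and 3072 falls, and a correction for GC content and length gave 1552 rises and 1822 falls. Across genes, which are not independent replicates, the log2 fold change had a Spearman's rho of 0.34 with transcript length and -0.36 with GC content. With DMSO replicate 1 left out these were 0.14 and -0.22. At least 2-fold rises and falls numbered 323 and 208 with a pseudocount of 0.25, 67 and 32 with 5, and 138 and 85 among genes of at least 5 CPM.

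**Figure D3:**
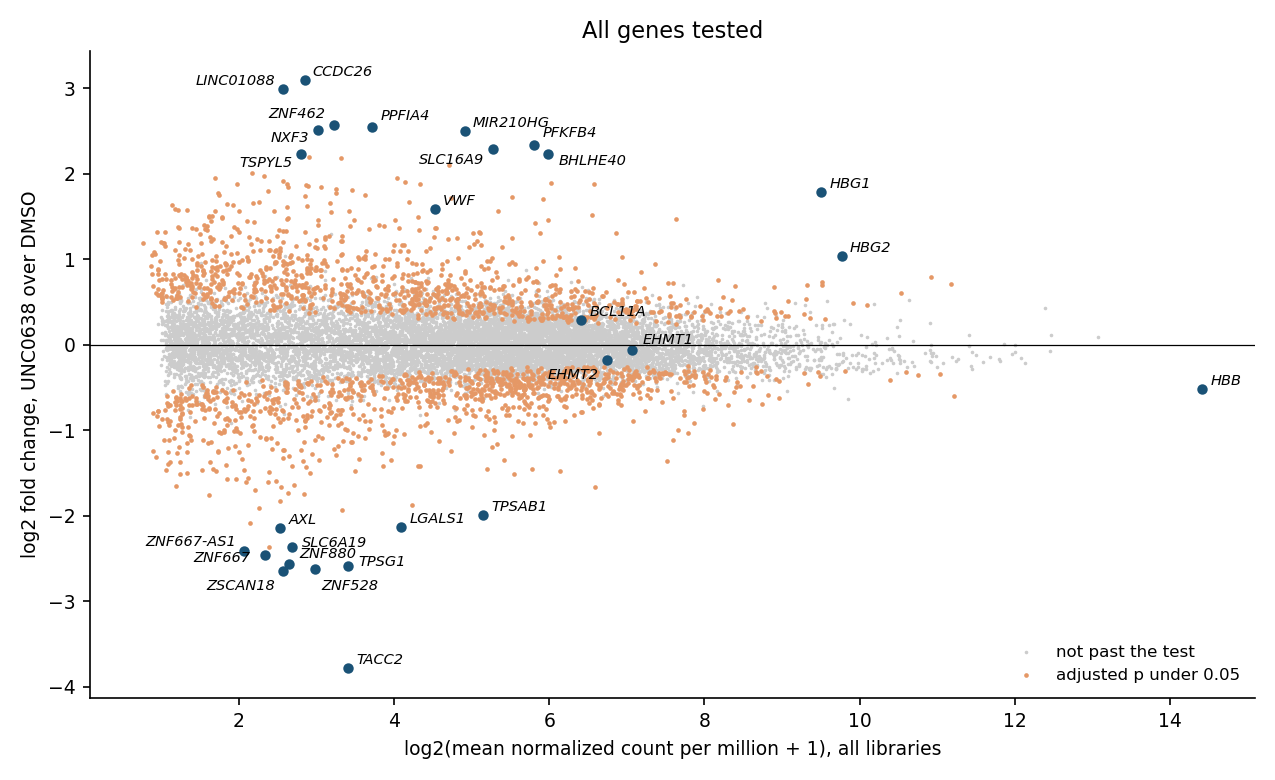
Log2 fold change of UNC0638 over DMSO against the log2 of the mean normalized count per M plus 1, for all 12267 genes tested. Genes past an adjusted p of 0.05 are orange and the rest gray, and labelled blue points mark the genes of the naming rule and other genes given in the text, from TACC2 at -3.79 to CCDC26 at 3.10.

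Several groups of erythroid genes held more rises than falls. Of 22 late erythroid maturation genes 12 rose and 0 fell (13 and 0 adjusted over the list alone). Among them, TRIM10 rose 1.92-fold (limma adjusted p = 0.000334) and the carbonic anhydrase CA1 1.73-fold (adjusted p = 0.00174). The glucose transporter SLC2A1, also a hypoxia-response gene, rose 1.66-fold (adjusted p = 0.00233). BPGM, which makes the hemoglobin ligand bisphosphoglycerate, rose 1.42-fold (adjusted p = 0.00648). The list's camera adjusted p was 0.000158, and the adjusted p with an estimated correlation was 0.29. Of 25 red cell membrane and blood group genes 7 rose and 0 fell (9 and 1 adjusted over the list alone). Its camera adjusted p was 0.000469, and adjusted p = 0.154 with an estimated correlation. The urea transporter SLC14A1 rose 2.37-fold (adjusted p = 0.00072) and the anion exchanger SLC4A1 1.63-fold (adjusted p = 0.0138).

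Of 20 genes of heme biosynthesis and iron uptake 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.109). The heme synthesis enzymes ALAD (1.6-fold, limma adjusted p = 0.0015) and CPOX (1.62-fold, adjusted p = 0.00341) and the mitochondrial iron importer SLC25A37 (1.52-fold, adjusted p = 0.0107) rose. The heme-degrading HMOX1 fell 1.92-fold (adjusted p = 0.00599). Of 12 early erythroid progenitor genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.709). CYTL1 rose 2.49-fold, and the transcription factors GATA2 and MYC fell 1.71-fold and 1.56-fold. In this list 5 rose and 4 fell without DMSO replicate 1. In DMSO replicate 1 the median of the late erythroid list lay 0.12 (log2) above the other DMSO libraries, and that of the adult globins 0.72. Without DMSO replicate 1, 15 late erythroid, 17 membrane and 12 heme genes rose, and the heme list passed (camera adjusted p = 9.94e-05). The heme list also passed with quantile normalization (0.0251), quality weights (0.00178) and the GC and length correction (0.0139). Without DMSO replicate 2 or 3, 6 and 7 late erythroid and 3 and 5 membrane genes rose. Without UNC0638 replicate 1, 2 or 3, 6, 7 and 6 late erythroid genes rose, and in each case 2 membrane and 2 heme genes. SLC4A1 and SLC25A37 were among those lost without each UNC0638 library (adjusted p of 0.0655 to 0.0707 and 0.0576 to 0.065).

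Markers of megakaryocytes, the platelet precursors that share a progenitor with erythroid cells, rose together: 13 of 15 rose and 0 fell (14 and 0 adjusted over the list alone). The camera adjusted p was 4.00e-09, and the adjusted p with an estimated correlation was 0.104. VWF, von Willebrand factor, rose 3.01-fold, from 10.4 ± 0.94 to 33.6 ± 6.12 CPM (log2 fold change 1.59, SE 0.14, limma adjusted p = 0.000555). PLEK rose 2.39-fold, the integrin ITGB3 2.26-fold and P-selectin, SELP, 2.21-fold. Without UNC0638 replicate 3, 8 of the 15 genes rose. Of 14 mast cell, basophil and eosinophil markers 2 rose and 4 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.0822). The tryptases TPSAB1 (3.98-fold lower, adjusted p = 0.00106) and TPSB2 (3.67-fold lower, adjusted p = 0.00213), nearly identical and uncertain individually, fell, as did ENPP3 (2.57-fold lower, adjusted p = 0.000985) and GATA2. The IgE receptor subunits MS4A2 and FCER1A rose, with log2 fold changes of 0.78 and 0.75 (adjusted p of 0.0125 and 0.0279). The list held 0 rises without UNC0638 replicate 1 or 2, and 1 without UNC0638 replicate 3, DMSO replicate 2 or DMSO replicate 3. It passed without DMSO replicate 1 (camera adjusted p = 0.0413), with 3 rises and 6 falls. In that library its median lay 0.31 (log2) above the other DMSO libraries, and TPSAB1 was at 79.2 CPM against 44.1 and 44.9.

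Of 18 stem and progenitor cell markers 7 were measured, and CD34 was not among them. In this list 3 rose, the transcription factors MEIS1 (2.14-fold), FLI1 (2.07-fold) and HOXA10 (1.99-fold), and 0 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.23). Of 15 neutrophil lineage markers 8 were measured and 0 passed (0 adjusted over the list alone, camera adjusted p = 0.989). Their median was -0.07 while camera's direction was up, and in DMSO replicate 1 it lay 0.64 (log2) above the other DMSO libraries. Either without that library or with quality weights, 3 members of the neutrophil list rose, MPO, CSF3R and LCN2, and 1 fell, RNASE2. RNASE2, also an eosinophil gene and so not specific to neutrophils, fell without DMSO replicate 2 too (limma adjusted p = 0.0378). RNASE2 passed with quantile normalization (0.0482) and with the replicate block (0.0101), and MPO with fixed sums (0.0475 without globin genes and 0.0439 over all genes). Both passed with the GC and length correction (0.0124 and 0.00653). Without DMSO replicate 1 or with quality weights, 4 stem and progenitor cell markers rose and 2 fell. Of 17 monocyte and macrophage markers 5 were measured, and 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.0841). This list passed without UNC0638 replicate 2 (0.0475) and with the GC and length correction (0.0389). HLA-DRA (3.69-fold, limma adjusted p = 0.000313) and CD74 (2.75-fold, adjusted p = 0.000475), which serve antigen presentation, rose. In every DMSO library HOXA10, HLA-DRA and CSF3R were under 1.25 CPM, the lowest maximum of any gene. Their rows thus rest on the UNC0638 libraries. CD68 fell 1.79-fold (adjusted p = 0.0115), a call lost without UNC0638 replicate 2 (0.0582) or 3 (0.0586). The 16 lymphocyte markers were not analysed here.

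**Figure D4:**
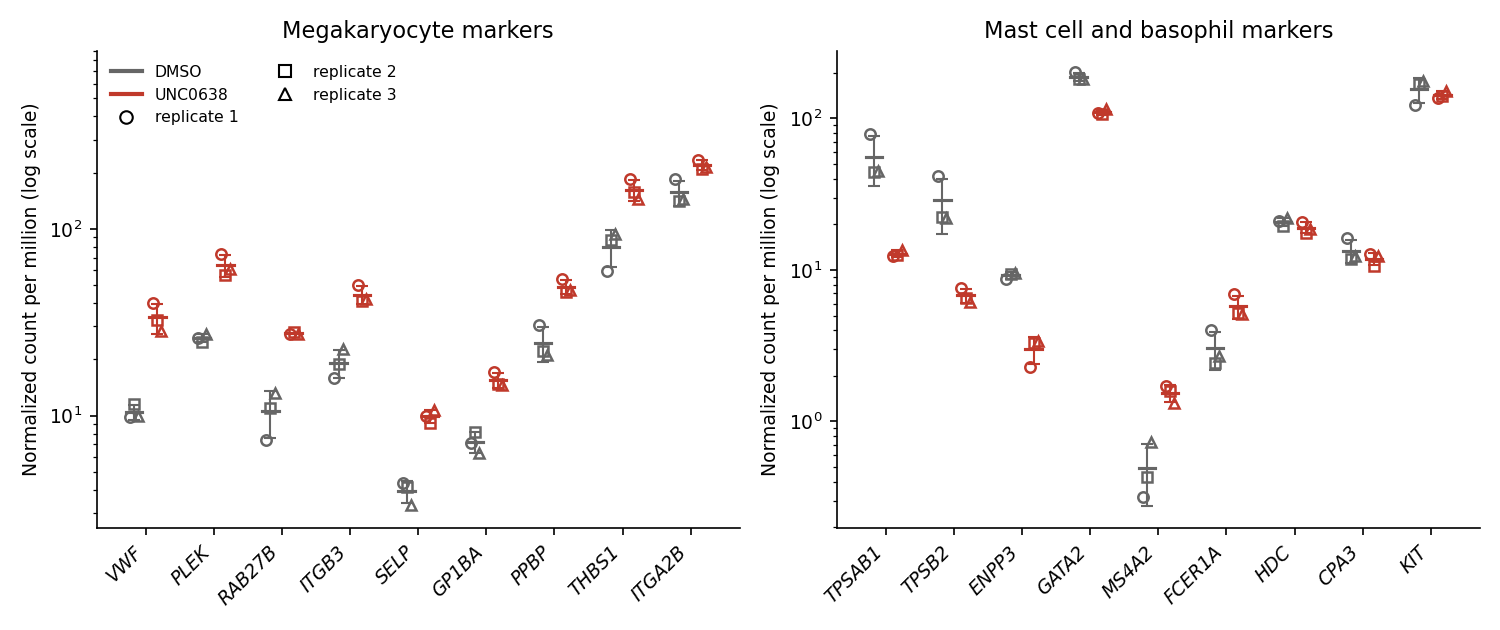
Normalized counts per M on a log scale of megakaryocyte markers (left) and mast cell and basophil markers (right) in each library, by group (color) and replicate (symbol), with the group mean as a line and the SD (n = 3) as error bars. VWF was 3.01-fold higher and TPSAB1 3.98-fold lower with UNC0638, while HDC, CPA3 and KIT did not pass the test.

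Of 14 heat shock and immediate early genes 1 rose and 7 fell (2 and 7 adjusted over the list alone). The list's camera adjusted p was 0.0466, and adjusted p = 0.691 with an estimated correlation. The heat shock chaperones HSPA1A (2.23-fold lower, limma adjusted p = 0.00131), HSPA1B (1.89-fold lower, adjusted p = 0.00296) and HSPA8 (1.51-fold lower, adjusted p = 0.0067) fell. The immediate early transcription factor JUN rose 2.96-fold (adjusted p = 0.000547). HSPA1A and HSPA1B are near copies of each other, and the list's median in DMSO replicate 1 lay 0.35 (log2) above the other DMSO libraries. The list's call was lost without DMSO replicate 1 (camera adjusted p = 0.0923), UNC0638 replicate 1 (0.0575) or UNC0638 replicate 2 (0.0712). It was also lost with quantile normalization (0.0978), quality weights (0.116) and the GC and length correction (0.137). Without UNC0638 replicate 1, 2 or 3, 3, 3 and 2 members fell, and HSPA8 lost its call without UNC0638 replicate 3 (adjusted p = 0.0535).

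Of 23 cholesterol biosynthesis genes 7 rose and 0 fell (7 and 0 adjusted over the list alone). The camera adjusted p was 0.0012, and adjusted p = 0.647 with an estimated correlation. STARD4, a sterol carrier, rose 1.85-fold, HMGCS1, an early enzyme of the pathway, 1.62-fold and SC5D, a late enzyme, 1.59-fold. Without DMSO replicate 2 or 3, 3 and 4 members rose, and without UNC0638 replicate 1, 2 or 3, 1, 3 and 1. With DMSO replicate 1 left out, 11 cholesterol genes rose (17 with quality weights), though STARD4 lost its call (limma adjusted p = 0.0845). STARD4 and HMGCS1 lost theirs without UNC0638 replicate 1 (0.0571 and 0.0524) or 3 (0.0713 and 0.072). Of 21 p53 targets and apoptosis genes 5 rose and 0 fell (7 and 0 adjusted over the list alone). The camera adjusted p was 0.0147, and adjusted p = 0.31 with an estimated correlation. TP53INP1 rose 2.21-fold and the antiproliferative BTG2 1.54-fold. In this list 10 rose without DMSO replicate 1 and 2 without UNC0638 replicate 1 or 3.

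Of 19 genes of the unfolded protein and integrated stress response 3 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.774). The lipoprotein receptor gene VLDLR rose 3.60-fold and the chaperone HSPA5 fell 1.62-fold. In this list 10 rose and 4 fell without DMSO replicate 1. Of 24 interferon-stimulated genes 17 were measured, and 3 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.26). XAF1 rose 1.78-fold and BST2 fell 1.44-fold, a call lost with the filter of 5 CPM (limma adjusted p = 0.0536) and without trend or robust variance (0.0514). Without DMSO replicate 2 or any 1 of the UNC0638 libraries, 1 interferon-stimulated gene rose and 0 fell, and without DMSO replicate 1, 5 rose and 2 fell. Of 22 lysosome and autophagy genes 2 rose, PSAP 1.45-fold and CTSL 1.49-fold, and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.0822). The list passed without DMSO replicate 1 (0.000386, 11 rises), and with a fixed sum without globin genes (0.0321), quantile normalization (0.0301), quality weights (0.00178) and the GC and length correction (0.00273). Without each of the other libraries the call of CTSL, which encodes a cathepsin protease, was lost (limma adjusted p of 0.054 to 0.108).

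Of 27 G1/S cycle genes 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.989). The fall was that of UNG, a DNA repair glycosylase, 1.37-fold, a call lost without UNC0638 replicate 1 (limma adjusted p = 0.0554) or 3 (0.0513). In this list 7 rose and 2 fell without DMSO replicate 1, and 10 rose and 1 fell with quality weights. Of 30 G2/M cycle genes 2 rose, the mitotic genes BUB1 and ECT2, and 2 fell, UBE2C and CDC20 (0 and 0 adjusted over the list alone; camera adjusted p = 0.522). Without any 1 of the UNC0638 libraries 0 of these 30 passed, without DMSO replicate 1, 9 rose and 4 fell, and with quality weights 11 rose and 4 fell. With a fixed sum of all genes BUB1 (0.051) and ECT2 (0.0658) lost their calls, ECT2 also with a fixed sum without globin genes (0.0633), and CDC20 lost its call with the filter of 5 CPM (0.0503) and without trend or robust variance (0.0616). Of 50 cytosolic ribosomal protein genes 0 passed (0 adjusted over the list alone). Their median log2 fold change was -0.24, with a camera adjusted p of 0.00122 and an adjusted p of 0.766 with an estimated correlation. In DMSO replicate 1 the median of these genes lay 0.67 (log2) above the other DMSO libraries. Camera's call was lost without that library (adjusted p = 0.475) and with quality weights (0.402), where in both cases 2 members rose and 3 fell. Of 15 mitochondrially encoded genes 0 rose and 1 fell, MT-ND2 at 1.24-fold lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.26). In this list 2 rose and 6 fell without DMSO replicate 1, and 2 rose and 5 fell with quality weights. Of 15 replication-dependent and linker histone genes 10 were measured, and 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.37). The call of MT-ND2 was lost without each library other than DMSO replicate 1 (adjusted p of 0.083 to 0.198) and under 5 other settings (0.0503 to 0.163), and 0 histone genes rose without any 1 of those libraries. Among histone genes 2 rose and 2 fell with quality weights.

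Among genes that act on histone H3 methylation, the H3K9 demethylases KDM3A (1.86-fold, log2 fold change 0.89, SE 0.15, limma adjusted p = 0.00747) and KDM4B (1.49-fold, adjusted p = 0.0104) rose. They were 2 of 9 measured, and 0 fell (2 and 0 adjusted over the list alone). The camera adjusted p was 0.00946, adjusted p = 0.66 with an estimated correlation and 0.0661 with quality weights. KDM3A, also a hypoxia-response gene, was at 101, 85.0 and 128 CPM in UNC0638 replicates 1, 2 and 3. KDM4B was at 117, 109 and 140 CPM, in both cases the order of PFKFB4 (87.3, 43.7 and 152). Whether these rises belong to the hypoxia response was not tested. The call of KDM3A was lost without DMSO replicate 1 (adjusted p = 0.0583), a library in which the list's median was -0.48 (log2) relative to the other DMSO libraries, while 4 members of the list rose without it. Of 16 H3K9 methyltransferases and partners 0 passed (0 adjusted over the list alone; camera adjusted p = 0.989), while without DMSO replicate 1, 2 rose and 3 fell, and with quality weights 4 and 4. Of 24 imprinted genes 9 were measured, and 4 rose and 1 fell (5 and 1 adjusted over the list alone). The camera adjusted p was 0.0276, and adjusted p = 0.31 with an estimated correlation. DLK1, a Notch-related growth regulator, rose from 0.29 ± 0.16 to 2.34 ± 0.051 CPM (SD, n = 3) and MEST from 12.7 ± 0.79 to 23.3 ± 3.52. In every DMSO library DLK1 was under 1.25 CPM, the lowest maximum of any gene, so its row rests on the UNC0638 libraries. PLAGL1 rose 1.57-fold, NAP1L5 rose 1.28-fold and SLC22A18 fell, with a log2 fold change of -0.52. Without any 1 of the UNC0638 libraries 2 of these genes rose, and without DMSO replicate 2, UNC0638 replicate 1 or UNC0638 replicate 3, 0 fell. Without DMSO replicate 1, 6 rose and 1 fell. Of 27 germline and cancer-testis genes 3 were measured, and DPPA4, a gene of pluripotent cells, rose from 1.5 ± 0.57 to 8.32 ± 0.90 CPM. On the log2(value + 1) scale this was 3.78-fold (adjusted p = 0.000689). In that list 0 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.499).

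**Figure D5:**
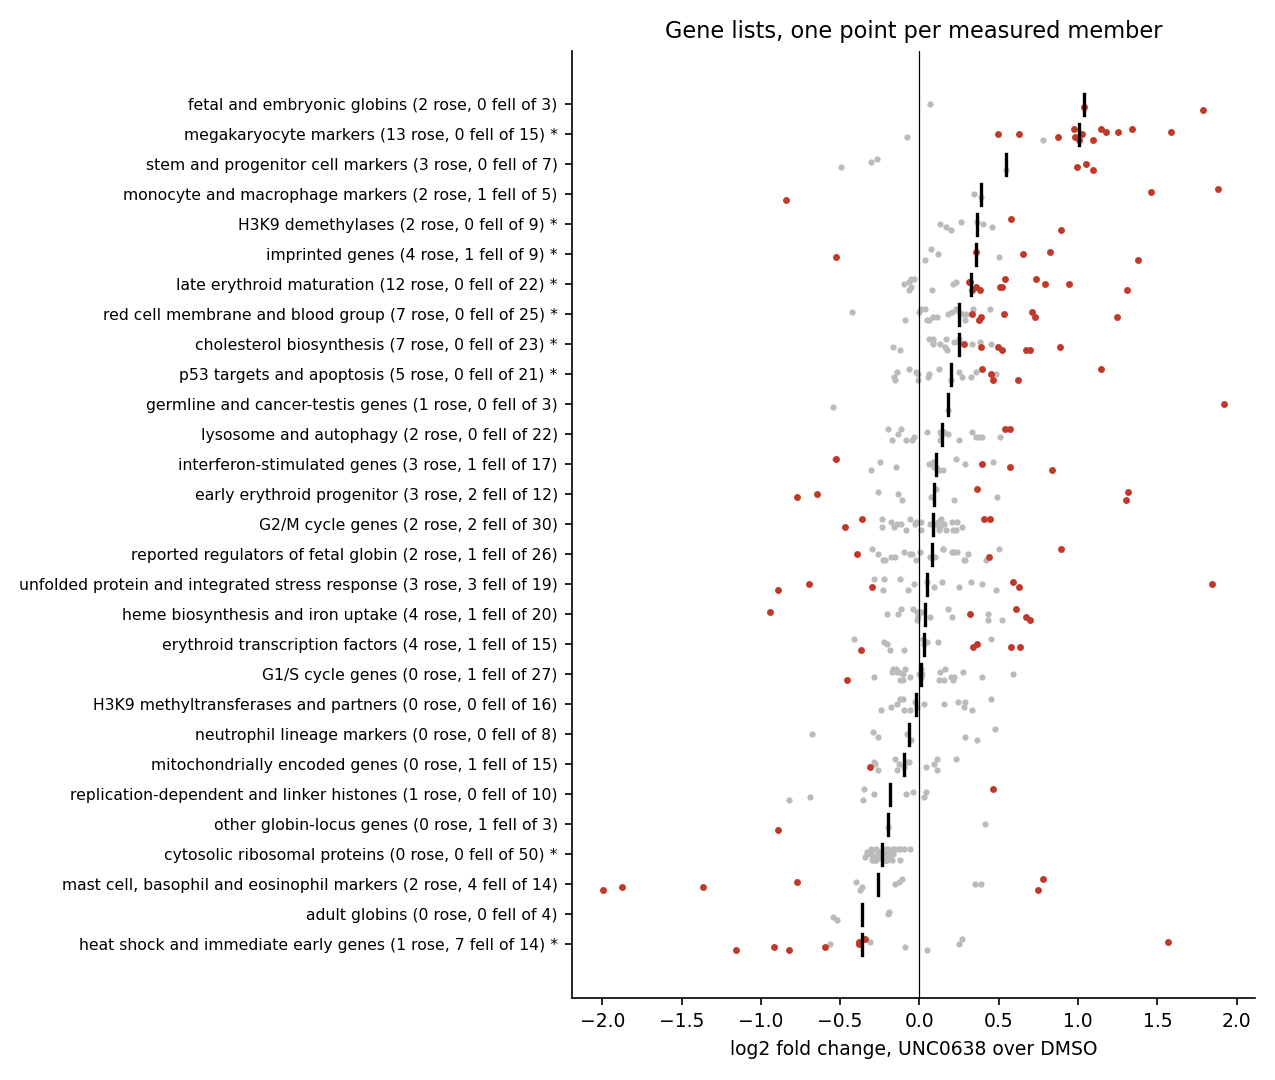
Log2 fold change of UNC0638 over DMSO for each measured member of 29 gene lists, red where the adjusted p was under 0.05 and gray otherwise, with a black bar at the list's median and an asterisk where camera's adjusted p was under 0.05. The megakaryocyte list has 13 of 15 members in red, and the ribosomal protein list lies around its median of -0.24 with no member in red.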

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

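Library quality weights and the GC and length correction were chosen after the data were seen. Of the 2103 genes called, 0 changed sign under any alternative run. Counts at least 2-fold were 323 up and 208 down with a pseudocount of 0.25, 67 and 32 with 5, and 138 and 85 with the filter of 5 CPM, as these settings stretch or shrink low genes or leave them out. Quality weights gave 3118 up and 3072 down, and the GC and length correction 1822 down; the cause was not tested. Leaving out a library gave 381 to 2525 genes up and 362 to 2495 down, the highest without DMSO replicate 1, with 186 to 235 up and 121 to 159 down at least 2-fold; fewer samples account for part of the losses. The filter of 1 CPM removed no gene, so its absence tests nothing. The fetal share difference stayed between 7.56 and 8.09 points without each library and was 7.95 with HBG1, HBG2 and HBB alone as denominator. Without each library 7 to 10 lists were called up and 1 to 2 down. With an estimated correlation 0 lists were called up and 0 down, with fry 11 and 1, with the GC and length correction 11 and 1; quantile normalization called 1 down and quality weights 0 (ribosomal proteins adjusted p = 0.402, heat shock genes 0.116), the cause not tested. Of 138 named genes, 95 passed the test and 0 of those reversed. Quality weights, among others, brought EHMT1, EHMT2, BCL11A, MYB, HBB, HBD, HBBP1 and HBE1 (0.436, adjusted p = 0.00471) past the test, the cause not tested. With these weights HBB (-0.325) and HBD (-0.229) lay close to their values without DMSO replicate 1 (-0.319 and -0.228). Calls gained under both settings are therefore not independent support. Reversed genes, none past the test in the comparison as reported and the cause not tested, were KLF1 (log2 0.0617 with weights and 0.197 with the GC and length correction, where it passed at adjusted p = 0.0251), HBA2 (0.0261 and 0.176), HBA1 (0.0196 and 0.146), HBQ1 (0.0456 and 0.204), GATA1 (0.0281 with the correction) and ZBTB7A (-0.000937 with weights). Without each library in turn KLF1 went from -0.188 to 0.0679, HBA2 from -0.330 to 0.0384, HBA1 from -0.359 to 0.0471 and HBQ1 from -0.330 to 0.0413, the highest each time without DMSO replicate 1. HBE1 went from -0.139, without DMSO replicate 2, to 0.330, without DMSO replicate 1.

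With the replicate block, 1342 genes rose and 1209 fell (211 and 138 at least 2-fold), 8 lists were called up and 3 down, gaining the fetal and embryonic globins and the mast cell list (camera adjusted p = 0.0415 for both), and the fetal share difference was 7.80 points (exact sign-flip p = 0.25, the smallest that 3 pairs allow). Same-numbered libraries deviated together with correlations across genes of 0.21, 0.11 and 0.08, not all over 0.1. DMSO replicate 3 correlated more with UNC0638 replicate 2 (0.10) than with its own number. The other mismatched pairs lay between -0.19 and 0.05, and each UNC0638 library correlated most with the DMSO library of its own number. Because not all same-numbered pairs exceeded 0.1, the numbers were not taken as pairs, though this check cannot exclude pairing. Deviations from a mean of 3 libraries are not independent, DMSO replicate 1 stands apart, and the sample titles share their numbers between the groups. The planned count test was not run, since whole reads could not be recovered by a single step per library. Depth limits genes near 1 CPM, where 1 read is worth 0.0447 to 0.0695 CPM.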

Other observations

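All tests in this part except those on the zinc finger genes, the hypoxia-response genes and the first test of a later erythroid stage were chosen after the results they measure were seen. A group of genes not described above was that of MHC class II antigen presentation, looked up after CD74 and HLA-DRA were seen to rise. Of 8 other class II genes measured, 7 rose and 0 fell in limma's test, among them HLA-DMA (from 4.40 ± 0.50 to 10.8 ± 0.82 CPM, 2.19-fold, adjusted p = 0.000918), HLA-DPA1 (1.62-fold, adjusted p = 0.0185) and the class II transactivator CIITA (1.59-fold, adjusted p = 0.0491). The level of 3 of the 7, not named here, can reflect a donor's genotype, and without those genes 4 of 5 rose. Of these 5, 1 rose without UNC0638 replicate 1 or 3, and 2 without DMSO replicate 2. Within the beta globin locus, the noncoding RNA gene BGLT3, chosen after its values were seen and lying on chromosome 11 from 5244554 to 5245546 of GRCh38, rose from 6.51 ± 1.48 to 26.7 ± 2.02 CPM (3.73-fold, adjusted p = 0.000441).

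The real grouping called 2103 genes and 9 lists. Among the 10 ways to divide the 6 libraries into 3 and 3, the highest of the others called 0 genes (1 split reached the real count, itself) and 15 lists (4 splits reached the real count, itself included), and 10 splits are too few for a share under 0.05. The 3 other splits with 10 to 15 lists each put DMSO replicate 1 with a pair of UNC0638 libraries, the other 6 called 2 to 6 lists, and the cause of these counts was not tested.

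Zinc finger genes of chromosome 19 were frequent among the falls: 76 of 218 fell and 1 rose, with 32 of the falls at least 2-fold, against 24 falls and 16 rises among 240 zinc finger genes of other chromosomes. Leaving out the 7 seen beforehand, 69 of 211 fell, a share above that on other chromosomes (Fisher's exact test, two-sided, p = 2.73e-09; genes of a cluster are not independent). Genes outside this family matched on GC content, length and level fell in 4.44% of cases (95% of draws between 1.83% and 7.34%). That was 30.4 percentage points below the 34.9% of all 218, the 7 seen beforehand included, which argues against these properties as the cause. Without the 7 the share was 32.7%, for which no separate matched draws were made. Other genes of chromosome 19 fell in 16.2% (108 fell and 17 rose of 668). Falls of chromosome 19 zinc finger genes numbered 130 without DMSO replicate 1, 147 with quality weights, and 52, 54 and 50 without UNC0638 replicates 1, 2 and 3. Those on other chromosomes numbered 53, 71, 11, 10 and 9, and their rises went from 16 to 42 without DMSO replicate 1 and to 61 with quality weights. Some of the falls of at least 2-fold on chromosome 19, such as ZNF471 (2.05 to 0.110 CPM) and ZNF677 (2.06 to 0.172), had rows that rest on the DMSO libraries. That the treatment lowers chromosome 19 zinc finger genes as a class stays a hypothesis, since reads shared between family members and indirect effects were not tested.

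Several of the largest rises (PFKFB4, MIR210HG, BHLHE40, PPFIA4) and VLDLR, EGLN3, KDM3A and SLC2A1 are known hypoxia-response genes. SLC2A1, also in the late erythroid list, was at 899, 829 and 1009 CPM in UNC0638 replicates 1, 2 and 3, the order of PFKFB4. Thus 50 other targets of the HIF transcription factors were listed before their values were seen. Of 46 measured, 19 rose and 1 fell (20 rose adjusted over the list alone), with a median log2 fold change of 0.40 at the 100th percentile of 10000 random lists matched on level, which fits an effect of UNC0638. The same list differed between UNC0638 libraries, with medians against the DMSO mean of 0.32, 0.11 and 0.82 in replicates 1, 2 and 3. In DMSO replicates 1, 2 and 3 they were 0.09, -0.07 and -0.06, so UNC0638 replicate 2 barely exceeded DMSO replicate 1. The difference of 0.61 between UNC0638 replicates 3 and 2 was also at the 100th percentile, which fits oxygen or cell density of single cultures. These libraries were taken as the highest and lowest in PFKFB4, itself a hypoxia-response gene, so they were not chosen independently of the list. Without UNC0638 replicate 3 the median was 0.21 and 9 genes rose, and without UNC0638 replicate 1 or DMSO replicate 2, 5 and 10 rose. Both explanations may hold, and the design holds no measure of oxygen or density.

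DMSO replicate 1 differed by over 2-fold from the mean of the other DMSO libraries in 101 genes (14 higher, 87 lower), against 0 between those libraries, with an SD 2.96 times that expected from them, which a single scaling factor cannot give. Across genes, which are not independent replicates, the difference fell with transcript length (Spearman's rho -0.596, and -0.06 between DMSO replicates 2 and 3) and rose with GC content (rho 0.45), so a loss of RNA or fragments that depends on length or GC may be a cause, though such trends are not confined to this library (UNC0638 minus DMSO replicates 2 and 3 had rho of 0.14 and -0.22). RNA of other blood cells may add to this. Among 15 neutrophil markers 8 were measured, each also present in the other libraries. As a list they lay at the 99.97th percentile of lists matched on level, GC and length. This was the highest of 4 lineage lists (monocyte 94.19, mast cell 92.23 and megakaryocyte 18.17, each inside the random range). The most abundant, RNASE2, which is not specific to neutrophils, was at 39.4 CPM against 21.7 and 25.2, and MPO at 15.4 against 11.3 and 13.2. Lists that mark no other lineage also lay outside the random range. The ribosomal proteins were at the 100th percentile, the H3K9 demethylases at 1.74 and the mitochondrially encoded genes at 0.01. The neutrophil percentile alone therefore cannot tell RNA of other cells from other causes. A later erythroid stage was left undecided: against lists matched on level, as planned, the late erythroid list lay at the 51.06th percentile (50.5 to 51.8 in 20 repeats, while a first run fell just under the bound of 50 set for excluding it), and after that result the test was changed to lists matched also on GC and length, giving the 20.83rd. The bound first set for that second test, 49, would have excluded a later stage, and it was lowered to 2.5 after the value was seen because a value inside the random range excludes nothing.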
